A study of Drosophila melanogaster with 6 samples.

How the data were processed

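RNA of wing imaginal discs was extracted with Trizol and sequenced on an Illumina NextSeq, per the labels' protocols. The series holds 3 control libraries (MS1096-Gal4) and 3 dNKAP RNAi libraries, grouped and numbered by their titles. The authors deposited 1 transcript table per library. Per the file headers each table has the layout that Cuffcompare writes for transcripts assembled from 1 library, with the closest reference transcript, a class code for the match, FPKM with lower and upper confidence bounds, read depth and transcript length. FPKM values, fragments scaled to transcript length and library size, were used as deposited by the authors. The deposited coverage column is a signal, the mean read depth per base of a transcript, not scaled to library size, per the file headers and the values. Per the submitters' processing notes the tools were FastQC, HTSeq and DESeq and the genome build dm6. Their versions, the aligner, the annotation release and the use of strand are not given in the sources used here. No column holds read counts, so the test fixed for normalized values was used in place of the one fixed for counts.

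The value of a gene was the sum of the FPKM of its transcripts with class codes for an exact match, a contained fragment, a new isoform that shares a junction, or other exonic overlap. Transcripts in other classes made up 0.267% to 3.70% of each library's FPKM and were left out of gene values. Of 17524 listed genes, 17428 were matched to a name through the Ensembl annotation of the same assembly (BDGP6, the assembly called dm6) or a table of FlyBase names, and 149 older identifiers were replaced through their transcripts. Coordinates are from that annotation. Depth was taken as read depth times transcript length summed over a library. The half-width of the deposited confidence bounds had a median of 7.47% to 8.81% of the value for transcripts between 10 and 50 FPKM. The library with the most bases, control replicate 2, had the narrowest bounds, and the one with the fewest, dNKAP RNAi replicate 1, the widest. Those bounds cover the estimate within a library and not the spread between replicates. No 2 libraries held identical values for any tested gene above 0 in all libraries.

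The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. Groups were compared with limma (version 3.58.1, R version 4.3.3) on log2(FPKM + 0.5), with a mean-variance trend, for genes with a mean of at least 1 FPKM over 6 libraries, Benjamini-Hochberg adjustment and a threshold of 0.05. Matrices and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. All tests are two-sided. The 44 gene lists, 1062 genes in all, cover signalling pathways, patterning, stress, repair, RNA processing, metabolism and markers of other cell types that a dissected disc can carry; 16 listed names had no match. The 43 lists with at least 3 tested genes were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists, and again with an estimated correlation and with fry. fry asks whether the genes of a list move one way on balance and does not compare them with other genes. Of the 6 lists past the threshold with the preset correlation, 0 held with an estimated correlation, and fry put 3 lists past it: DNA damage response and repair (fry adjusted p = 0.0113), JAK/STAT (0.0352) and Toll and Imd (0.0101). The 1 gene of the Toll and Imd list called over all genes, Dif, was listed at 0 in all controls. Transcript usage was tested with limma's diffSplice on transcripts with a mean of at least 1 FPKM in genes with at least 2 such transcripts, 4388 transcripts in all. For this test a newly assembled transcript was summed under its closest reference transcript. A value given under a reference transcript is therefore not the FPKM of that exact transcript alone.

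Named genes are CG6066; the 12 largest rises and 12 largest falls among genes past the threshold with separated groups and a mean above percentile 33.3 of tested genes; up to 4 members past the threshold from each list, or the 2 most abundant if none passed; 15 genes of disc growth, death and patterning whatever their values; and the 8 genes with the smallest adjusted p for transcript usage. The 12 largest rises and falls, and the 8 usage genes, were also named among features above 0 in every library, a choice made after the values of 0 had been seen. mre11, nbs and the examples listed at 0 (Act5C, RpS2) were likewise named after their values were seen.

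The tests were checked on simulated values for 5511 genes, drawn from each gene's mean and residual SD in the comparison of control with dNKAP RNAi, with 200 genes changed. The gene test recovered 49.3% of 1.5-fold, 62.7% of 2-fold and 90.9% of 4-fold changes, with 6.25% of calls false. With values set to 0 at the share seen in the tables it recovered 16.4%, 38.8% and 54.5%, with 5.19% of calls false. Those values of 0 were placed at random over genes and libraries. The share of false calls therefore does not carry over to genes listed at 0 throughout a group. In a simulation of 43 lists the 1 shifted list was called and 0 others. Genes were drawn independently there, so it does not show how often lists whose genes move together are falsely called. The estimated correlation was 0.117 for the DNA repair list and 0.908 for mitochondrially encoded genes. For transcript usage in 576 genes, 85.0% of 200 genes with a 4-fold shift were recovered, with 2.86% of calls false. So large a share of changed genes eases the cutoff of the adjustment, so these shares need not hold where few genes change. That simulation used transcripts above 0 in every library and set no values to 0. Its share of false calls does not carry over to usage calls that rest on values of 0.

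Alternatives fixed beforehand were median-ratio scaling, quantile normalization, other minimum means and pseudocounts, a replicate block, a minimum fold, read depth times length in place of FPKM, other list tests, other transcript filters, a gene-level F test and each library left out in turn. Alternatives chosen after seeing the data were genes above 0 in all libraries, values of 0 treated as missing, exact matches alone, every class code but overlap on the other strand, and quantile normalization for the lists. Genes whose exons overlap another gene, on either strand, are reported as uncertain because strand use is not stated.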

Results

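The data are RNA-seq libraries from *Drosophila melanogaster* wing imaginal discs, the larval epithelia that form the adult wing and notum. A control group of 3 libraries carried the MS1096-Gal4 driver alone, and a group of 3 libraries carried the driver with an RNAi transgene against dNKAP. MS1096-Gal4 is an insertion at Beadex (Bx) that drives UAS transgenes mainly in the wing pouch, so whole discs also contain cells with little or no hairpin. Each library listed 33445 to 33742 transcripts with an FPKM value, and 6022 to 6183 genes exceeded 1 FPKM. Read depth times transcript length summed to 4.81, 6.44 and 4.71 gigabases in control replicates 1 to 3 and to 4.14, 4.38 and 4.55 gigabases in dNKAP RNAi replicates 1 to 3. Log2 values of the 5511 tested genes above 0 in every library correlated at 0.974 to 0.977 between control libraries. They correlated at 0.967 to 0.971 between dNKAP RNAi libraries and at 0.946 to 0.958 between groups. Genes listed at 0 in a library did not enter these correlations. Adjusted p-values of genes are from limma with Benjamini-Hochberg adjustment over the genes tested, and fold changes are on the log2(FPKM + 0.5) scale, which understates changes of low genes. Nothing in the sources used here says that the replicates came from separate animals or crosses, so p-values measure the spread between these samples, which may be technical.

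The comparison asks how lowering dNKAP changes the wing disc transcriptome, and the target transcript itself was lower in every dNKAP RNAi library. CG6066 (FBgn0039488; chromosome 3R, 27115152 to 27116707, minus strand, dm6 coordinates) encodes the fly homolog of NKAP, a nuclear protein with reported roles in transcriptional repression and RNA splicing. Its level was 23.6, 22.8 and 26.6 FPKM in the control libraries and 13.96, 13.3 and 11.4 FPKM in the dNKAP RNAi libraries. The means were 24.4 ± 2.01 and 12.9 ± 1.33 FPKM (SD, n = 3 each), so CG6066 fell by 0.90 on the log2 scale (SE 0.11, limma adjusted p = 0.0146). The limma adjusted p was 0.0553 without control replicate 1, 0.0504 without control replicate 3 and 0.0584 without dNKAP RNAi replicate 2, and between 0.0402 and 0.0447 without each of the others. Against a minimum fold of 1.5, limma's treat test gave an adjusted p of 0.587. Reads of the hairpin, where it overlaps the transcript, would count toward CG6066.

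In discs with dNKAP RNAi, 6 genes of the DNA repair list, the unpaired cytokine genes, the glutathione transferase genes GstE3, GstE6 and GstE8 and the growth-signal gene Ilp8 rose, and fewer genes fell than rose. Arc1, which encodes a retrotransposon-derived capsid protein, had the largest rise among genes above 0 in every library, from 11.5 ± 3.44 to 692 ± 215 FPKM (SD, n = 3 each; log2 change 5.85, SE 0.32, limma adjusted p = 0.00108). Its neighbour and paralog Arc2 rose from 4.78 ± 0.986 to 67.4 ± 13.5 FPKM. Cul2, a cullin scaffold of ubiquitin ligases (chromosome 2L, 21658735 to 21663698), rose from 28.7 ± 2.88 to 200.1 ± 5.17 FPKM, with a log2 change of 2.79 (SE 0.09, limma adjusted p = 2.25e-04). Across 6506 tested genes, 209 were higher and 33 were lower in dNKAP RNAi with limma and Benjamini-Hochberg adjustment, and 1235 had an unadjusted p under 0.05. The 3 libraries of one group all lay above those of the other in 28.5% of tested genes, against 10% by chance.

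**Figure D1:**
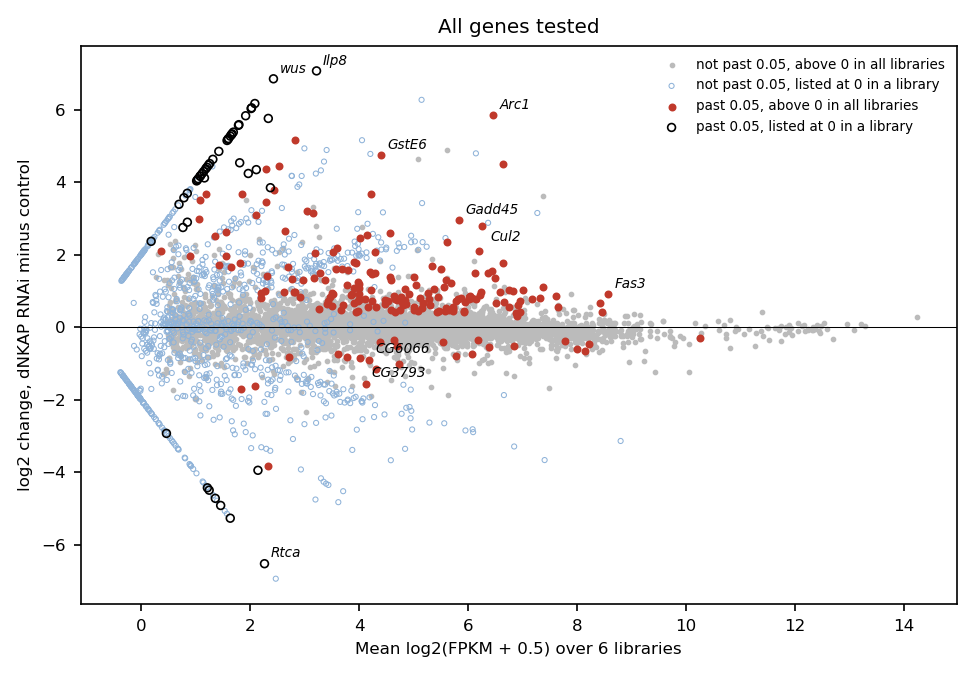
Change between groups (log2 FPKM + 0.5, dNKAP RNAi minus control, n = 3 libraries each) against mean log2 level for 6506 genes. Red points are past an adjusted p of 0.05 and above 0 in all libraries, black open points are past it and listed at 0 in at least 1 library, grey and blue points are not past it; 209 genes lie above and 33 below.

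Other genes with the largest rises among those above 0 in every library were CG42319 (0.960 ± 1.19 to 43.0 ± 9.39 FPKM), CG15784 (24.3 ± 18.7 to 472 ± 19.2 FPKM) and CG8620 (0.864 ± 0.792 to 28.0 ± 11.9 FPKM). The cytochrome P450 gene Cyp6d2 rose from 2.39 ± 1.38 to 24.9 ± 4.56 FPKM, rdog from 2.58 ± 0.844 to 26.1 ± 3.17 FPKM, Nt5b from 9.12 ± 1.04 to 59.5 ± 18.1 FPKM and Osi14 from 6.94 ± 1.46 to 43.1 ± 10.4 FPKM (SD, n = 3 each). The lncRNA gene lncRNA:CR44111 measured 0.0890, 0 and 0.588 FPKM in controls and 40.1, 34.2 and 36.0 FPKM in dNKAP RNAi (limma adjusted p = 0.00108). Among the falls, CG3793 went from 29.4 ± 1.253 to 9.70 ± 1.35 FPKM (log2 change -1.56) and the receptor phosphatase gene Ptp99A from 29.1 ± 2.04 to 12.9 ± 2.60 FPKM (log2 change -1.16). Acf, a chromatin remodelling subunit, fell from 37.2 ± 3.00 to 18.3 ± 1.82 FPKM, CG3649 from 21.4 ± 1.88 to 11.7 ± 1.60 FPKM and CG5447 from 17.7 ± 0.176 to 9.81 ± 0.777 FPKM. Gnpnat, an enzyme of UDP-N-acetylglucosamine synthesis, fell from 71.9 ± 5.46 to 41.4 ± 5.23 FPKM, and Echs1, a mitochondrial enoyl-CoA hydratase, fell from 354 ± 16.8 to 225 ± 15.5 FPKM. CG14715 fell from 87.0 ± 3.95 to 51.6 ± 2.81 FPKM and CG34445 from 15.4 ± 1.18 to 8.99 ± 0.918 FPKM. Dic1 (16.04 ± 2.15 and 8.40 ± 1.65 FPKM), CG4455 (28.4 ± 3.00 and 17.1 ± 2.42 FPKM) and asRNA:CR44850 (32.1 ± 3.77 and 19.7 ± 2.98 FPKM) had limma adjusted p of 0.0605, 0.0605 and 0.0755 over all tested genes. They passed the threshold when genes listed at 0 in a library were left out, at 0.0354, 0.0383 and 0.0481, a setting chosen after the values of 0 had been seen. Exons of another gene overlapped 76 of the 209 higher and 19 of the 33 lower genes, among them Cyp6d2, CG3793, Ptp99A, Acf, CG3649, CG14715 Echs1, Ilp8, Traf4, baz, crc and loco, and since strand use is not stated their values are uncertain. Without dNKAP RNAi replicate 1 or 3, 126 and 135 genes were higher, and after quantile normalization 187 were higher and 62 lower, so that the share of higher calls went from 86.4% to 75.1%. Calls ended, with limma adjusted p up to the value given, for CG3649 without any 1 library (0.105), for CG34445 (0.0980) and Ptp99A (0.0908) without any but dNKAP RNAi replicate 1, and for Gnpnat without any but dNKAP RNAi replicate 2 (0.0949). They also ended for CG42319 without control replicate 2 or any dNKAP RNAi replicate (0.0562), for CG15784 without any dNKAP RNAi replicate (0.0562), for Cyp6d2 without dNKAP RNAi replicate 1 or 3 (0.0525) and for Echs1 without dNKAP RNAi replicate 1 (0.0508), while CG8620, rdog, Nt5b, Osi14, lncRNA:CR44111, CG3793, Acf, CG5447 and CG14715 stayed under 0.05.

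A minority of the tested DNA repair genes passed the threshold in dNKAP RNAi, though 22 of 25 had a higher mean log2 value and 3 a lower one. In the list for DNA damage response and repair, 6 of 25 tested genes rose, 0 fell and 19 did not pass, and 8 rose when p was adjusted over the list alone. Ku80 and Irbp (the fly Ku70), which bind broken ends in end joining, rose from 7.63 ± 0.882 to 27.6 ± 3.00 FPKM and from 7.94 ± 1.37 to 28.3 ± 4.76 FPKM. The ligase gene DNAlig4 of the same pathway rose from 3.14 ± 0.226 to 10.98 ± 0.526 FPKM (log2 change 1.66, SE 0.11, limma adjusted p = 0.00168). All 3 genes of the Mre11-Rad50-Nbs complex rose as well, rad50 from 10.1 ± 0.438 to 23.6 ± 1.64 FPKM, mre11 from 33.3 ± 0.859 to 78.9 ± 12.7 FPKM and nbs from 7.74 ± 0.935 to 14.3 ± 0.858 FPKM (SD, n = 3 each). The list had a median log2 change of 0.33 and moved up against other genes in limma's camera test with a preset correlation (adjusted p = 1.78e-04). With a correlation estimated per list, the adjusted p of this list was 0.869, and of the 43 lists tested none was past 0.05 in that form of the test. After quantile normalization the list median was 0.155. Other genes of double-strand break repair in the list, among them spn-A, okr, Brca2, PolQ, tefu and Blm, did not pass. Exons of another gene overlap those of mre11 and nbs. p53, the DNA damage regulator, was listed at 0 in all 6 libraries and was not tested.

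**Figure D2:**
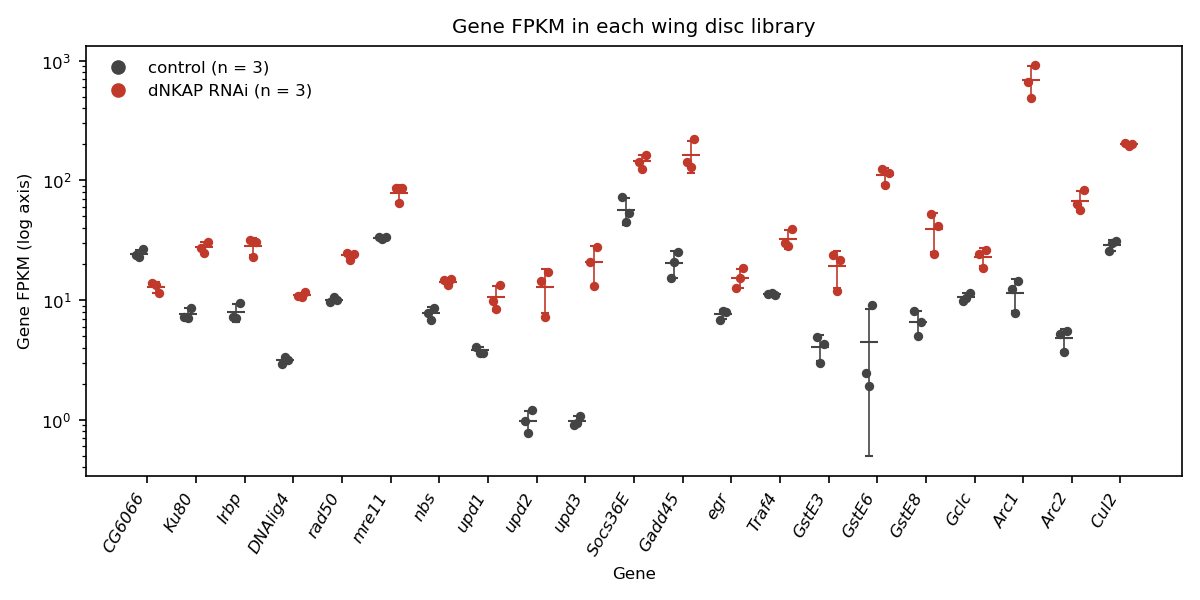
FPKM (log axis) of CG6066 and of genes of the repair, JAK/STAT, JNK and glutathione transferase lists, with Arc1, Arc2 and Cul2, in each library. Points are libraries (grey control, red dNKAP RNAi, n = 3 each), dashes means and bars SD; CG6066 is lower in all 3 dNKAP RNAi libraries and the other genes shown are higher in all 3.

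Some JNK target genes rose in dNKAP RNAi. In the list of JNK pathway targets 5 of 16 tested genes rose, 0 fell and 11 did not pass, with 8 higher when adjusted over the list alone. The unpaired genes, which encode the ligands of JAK/STAT signalling, rose: upd3 from 0.975 ± 0.0909 to 20.6 ± 7.41 FPKM (log2 change 3.78, SE 0.29, limma adjusted p = 0.00329). Likewise upd2 rose from 0.985 ± 0.209 to 12.9 ± 5.10 FPKM and upd1 from 3.79 ± 0.256 to 10.6 ± 2.53 FPKM. These genes lie near each other on chromosome X, with upd2, upd3 and upd1 starting at 18240654, 18277233 and 18305354. Their changes may therefore not be independent in the lists that hold them. Gadd45, a stress-inducible gene, rose from 20.4 ± 5.05 to 164 ± 50.2 FPKM. Ilp8, a relaxin-like peptide that delays development when disc growth is disturbed, was listed at 0, 0 and 1.56 FPKM in controls and at 104, 74.3 and 161 FPKM in dNKAP RNAi (limma adjusted p = 0.00630). The JNK phosphatase gene puc measured 30.6 ± 1.59 and 43.2 ± 8.25 FPKM (limma adjusted p = 0.190) and Mmp1 65.2 ± 13.8 and 95.3 ± 17.7 FPKM (limma adjusted p = 0.247), and neither passed the threshold. In the JAK/STAT list, which shares upd1, upd2 and upd3 with the JNK targets, 4 of 12 tested genes rose and 0 fell, with 5 higher when adjusted over the list alone. Socs36E, a feedback inhibitor of the pathway, rose from 57.0 ± 14.3 to 144 ± 19.6 FPKM. Median log2 changes were 0.51 for JNK targets and 0.23 for JAK/STAT, and camera adjusted p with the preset correlation were 4.55e-04 and 0.00388. The adjusted p with an estimated correlation was 0.917 for JNK targets and 0.869 for JAK/STAT. In the list of JNK pathway components (camera adjusted p = 0.891) 2 of 14 rose, the adaptor gene Traf4 from 11.2 ± 0.173 to 32.6 ± 5.997 FPKM and the TNF ligand gene egr from 7.63 ± 0.682 to 15.4 ± 2.90 FPKM. Adjusted over the list alone, 2 were higher and 1 lower. egr was also the 1 of 12 tested apoptosis genes that rose, over all genes and over the list alone (list camera adjusted p = 0.860). The death genes rpr and hid did not pass: rpr measured 12.5 ± 3.36 and 12.2 ± 1.97 FPKM, and hid was listed at 7.70 FPKM in control replicate 3 and at 0 elsewhere. Calls ended, with limma adjusted p up to the value given, for egr without any library but dNKAP RNAi replicate 1 (0.136), for Socs36E without any but control replicate 1 (0.114), for upd1 without any control or dNKAP RNAi replicate 1 (0.0850) and for upd2 without dNKAP RNAi replicate 1 (0.0584), whereas upd3, Ilp8, Gadd45 and Traf4 stayed under 0.05.

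A few detoxification genes rose past the threshold in dNKAP RNAi, while 18 of 24 had a higher mean log2 value and 6 a lower one. In the list of oxidative stress and glutathione transferase genes 4 of 24 tested genes rose, 0 fell and 20 did not pass, with 8 higher and 2 lower when adjusted over the list alone. GstE6 rose from 4.49 ± 3.99 to 110 ± 17.7 FPKM (log2 change 4.75, SE 0.55, limma adjusted p = 0.0129), GstE8 from 6.55 ± 1.55 to 39.5 ± 14.2 FPKM and GstE3 from 4.08 ± 1.01 to 19.1 ± 6.42 FPKM. These genes lie in 1 cluster of similar copies on chromosome 2R, and reads shared between copies make their separate values uncertain. Gclc, the catalytic subunit of the enzyme that starts glutathione synthesis, rose from 10.6 ± 0.826 to 23.0 ± 3.96 FPKM. The list median was 0.37, with a camera adjusted p of 0.0244, and the adjusted p with an estimated correlation was 0.917. After quantile normalization the median was 0.24. The camera adjusted p of this list was 0.0572 without control replicate 3, 0.0722 without dNKAP RNAi replicate 1 and 0.0721 without dNKAP RNAi replicate 3. In the list for integrated and proteotoxic stress (camera adjusted p = 0.690) 2 of 16 rose: crc, the fly ATF4, from 302 ± 17.9 to 406 ± 19.4 FPKM and PPP1R15, a regulatory subunit that directs dephosphorylation of eIF2α, from 19.96 ± 1.70 to 27.9 ± 0.675 FPKM. Adjusted over the list alone, 4 were higher and 2 lower. Xrp1 measured 215, 213 and 157 FPKM in controls and 0, 325 and 899 FPKM in dNKAP RNAi (limma adjusted p = 0.749). Calls ended, with limma adjusted p up to the value given, for GstE6 without control replicate 1 or any dNKAP RNAi replicate (0.0623), for GstE8 (0.0855), GstE3 (0.123) and Gclc (0.0937) without any library but dNKAP RNAi replicate 2, and for crc (0.118) and PPP1R15 (0.144) without any 1 library.

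Transcripts of the mitochondrial genome were lower as a list in the camera test with the preset correlation alone, with no single gene past the threshold. All 10 tested mitochondrially encoded genes had a lower mean log2 value in dNKAP RNAi, the list median was -0.78, and the camera adjusted p was 4.57e-04. Their estimated correlation was 0.908, and with it the adjusted p was 0.917, while fry gave an adjusted p of 0.238. mt:CoIII measured 106 ± 26.1 and 57.0 ± 18.0 FPKM and mt:lrRNA 402 ± 140 and 308 ± 60.8 FPKM, and 0 genes were past 0.05 either over all genes or over the list alone. Both genes overlapped between groups. In control replicate 3 mt:CoIII was at 76.0 FPKM, against 76.7 FPKM in dNKAP RNAi replicate 2, and mt:lrRNA was at 242.8 FPKM, its lowest value in any library. The list of cytosolic ribosomal proteins, with 0 of 52 past 0.05 over all genes and 0 over the list alone, had a median of -0.07 and a camera adjusted p of 0.0244. After quantile normalization the median was -0.017 and the camera test, no longer past 0.05, pointed up (adjusted p = 0.981), and the adjusted p with an estimated correlation was 0.917. The camera adjusted p of the ribosomal list was 0.165 without control replicate 1, 0.0564 without dNKAP RNAi replicate 1 and 0.0721 without dNKAP RNAi replicate 3. RpL41 measured 18436 ± 7177 and 21377 ± 1579 FPKM and RpL23 9186 ± 476 and 9785 ± 1132 FPKM. For the nuclear genes of oxidative phosphorylation the median was -0.14 over 30 genes and the camera adjusted p 0.0528. The list was past 0.05, toward lower values, after median-ratio scaling (0.0425), with no filter (0.0422), without control replicate 2 (9.88e-04) and without dNKAP RNAi replicate 2 (0.0371). Of the alternatives chosen after seeing the data, it passed among genes above 0 in every library (0.00226), with exact matches alone (0.00870) and with every class code but overlap on the other strand (0.0464). RFeSP, the Rieske protein of complex III, was the 1 member past the threshold, over all genes and over the list alone, and was listed at 0 in every control library. The glycolysis list (13 tested, camera adjusted p = 0.690) had 1 gene that rose, the hexokinase gene Hex-A from 44.5 ± 0.0820 to 60.9 ± 1.70 FPKM, and 2 when adjusted over the list alone.

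**Figure D3:**
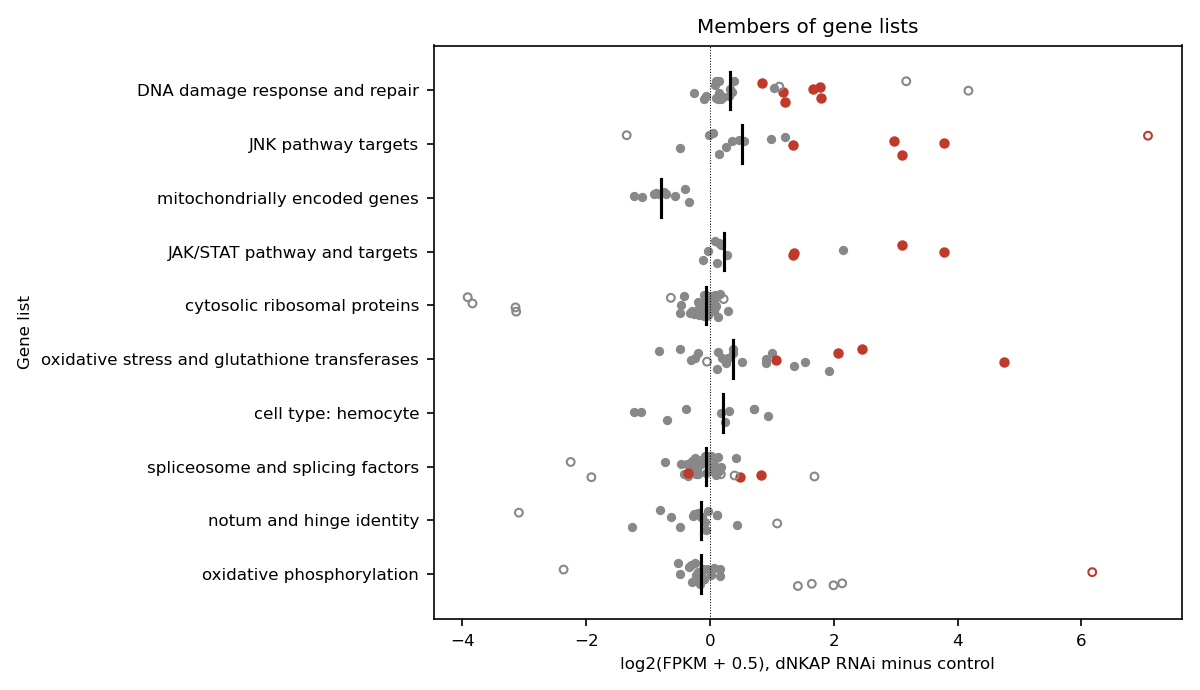
Log2 change (FPKM + 0.5, dNKAP RNAi minus control) of each tested member of the 6 gene lists past 0.05 with the preset correlation and of 4 further lists. Red marks genes past an adjusted p of 0.05, grey genes not past it, open points genes listed at 0 in at least 1 library, and black bars list medians; medians run from -0.78 for mitochondrially encoded genes to 0.51 for JNK targets.

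The RNA processing lists did not pass over all libraries. In the list of spliceosome and splicing factors (43 tested, median -0.07, camera adjusted p = 0.106) Prp31 of the tri-snRNP rose from 48.2 ± 2.59 to 86.1 ± 4.88 FPKM and cactin rose from 26.8 ± 1.44 to 37.7 ± 1.69 FPKM. Acn, a component that binds exon junction complexes, fell from 27.7 ± 0.956 to 21.5 ± 0.192 FPKM, and when adjusted over the list alone 2 genes were higher and 4 lower. Acn was also the 1 of 12 genes that fell, over all genes and over the list alone, for the exon junction complex and nonsense-mediated decay (camera adjusted p = 0.284). For R-loop and mRNA export factors (11 tested, camera adjusted p = 0.349) the export gene Nxt1 rose from 166 ± 12.13 to 245 ± 12.2 FPKM, the 1 member past 0.05 in both adjustments. Calls ended, with limma adjusted p up to the value given, for Acn without any 1 library (0.116), for cactin without any but control replicate 3 (0.0849) and for Nxt1 without any but control replicate 2 (0.0724), and exons of other genes overlap those of Prp31 and Nxt1. The spliceosome list was past 0.05, toward lower values, without control replicate 2 (0.0361) and without dNKAP RNAi replicate 2 (0.0494).

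The lists of genes that pattern the wing disc did not pass the threshold over all libraries, though the notum and hinge list lay close to it. The list for notum and hinge identity had a median of -0.14 over 17 genes (camera adjusted p = 0.0544) with 0 past 0.05 and 1 lower when adjusted over the list alone. It was past 0.05, toward lower values, without control replicate 1 (0.0201), dNKAP RNAi replicate 1 (0.0480) or dNKAP RNAi replicate 3 (0.0223), with no filter (0.0498) and among genes above 0 in every library (0.0427). Its members hth (106 ± 5.72 and 46.7 ± 19.7 FPKM, limma adjusted p = 0.108) and tsh (82.1 ± 1.83 and 74.5 ± 5.40 FPKM) did not pass. In the wing pouch list (25 tested, camera adjusted p = 0.802) only net, a repressor of vein formation, passed in both adjustments, and it was listed at 0 in every control library. For vg the values were 88.9 ± 20.6 and 102 ± 40.0 FPKM and for wg 33.2 ± 3.18 and 38.6 ± 5.51 FPKM. They were for ct 7.76 ± 0.210 and 6.68 ± 0.538 and for dpp 27.0 ± 1.84 and 30.1 ± 3.63, with limma adjusted p of 0.869, 0.460, 0.332 and 0.506. N was listed at 0, 80.4 and 72.1 FPKM in controls and at 76.2, 80.1 and 64.6 FPKM in dNKAP RNAi. Its ligand gene Delta was listed at 48.4, 0 and 60.2 FPKM in controls and at 0, 40.4 and 0 FPKM in dNKAP RNAi, and Bx at 0, 0 and 10.5 against 18.9, 18.8 and 0 FPKM. None of these 3 passed the threshold. The pathway lists had camera adjusted p of 0.208 for Notch (25 tested), 0.734 for Wingless (19), 0.280 for Dpp (15), 0.847 for Hedgehog (12), 0.784 for EGFR (11) and 0.628 for Hippo (22). The Wingless list was past 0.05 toward lower values with exact matches alone (0.0345). In the pathway lists 0 members passed over all genes or over the list alone, except Ilp8, which the Hippo list also holds. Their most abundant members had log2 changes of 0.03 for Tom, -0.36 for E(spl)malpha-BFM, -0.06 for arm, -0.78 for fz2, -0.33 for Ance, 0.48 for tkv, -0.24 for ihog, 0.21 for boi, 0.19 for cic and -0.04 for Egfr, none past the threshold.

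In the list for cell adhesion and polarity (26 tested, camera adjusted p = 0.734) 2 genes rose in both adjustments. Fas3, a septate junction adhesion protein, rose from 277 ± 10.9 to 522 ± 1.97 FPKM (log2 change 0.91, SE 0.05, limma adjusted p = 8.85e-04), and baz, the fly Par-3, from 21.3 ± 2.58 to 112 ± 23.8 FPKM. With exact matches to reference transcripts alone, the log2 change of Fas3 was -0.32 (limma adjusted p = 0.573). In the Toll and Imd list (10 tested, camera adjusted p = 0.0917) only Dif, listed at 0 in all controls, rose over all genes, and 2 were higher over the list alone. With no filter the camera adjusted p of this list was 0.0498. Among genes above 0 in every library, which leaves out Dif, it was 0.529, with a median log2 change of 0.13 over 7 members. The piRNA helicase gene spn-E rose from 1.00 ± 0.215 to 5.42 ± 1.01 FPKM, the 1 of 6 tested genes of the germline list to pass in either adjustment (camera adjusted p = 0.685). Its limma adjusted p was 0.0654 without dNKAP RNAi replicate 1 and 0.0576 without dNKAP RNAi replicate 3. Further lists with 0 genes past 0.05 over all genes, of 25 such lists in all, were ecdysone response (18 tested, camera adjusted p = 0.0800), replication-dependent histones (17, 0.219), ribosome biogenesis (26, 0.280), heat shock proteins (17, 0.498), cell cycle and mitosis (38, 0.690), sex-biased markers (7, 0.802), extracellular matrix (18, 0.883), chromatin silencing (23, 0.891) and chromosome segregation checkpoint (13, 0.936). Over the list alone 1 checkpoint gene was higher and the other lists had 0. The ecdysone list had a median of -1.13, with 14 of 18 members lower, and a median of -0.21 over its 13 members above 0 in every library. It was past 0.05, toward lower values, without dNKAP RNAi replicate 3 (camera adjusted p = 0.00183). With no filter the histone list, which had a median of 0.21 as reported, tested toward lower values (camera adjusted p = 1.09e-10). Their most abundant members had log2 changes of -1.24 for ImpE2, -0.10 for br, 0.20 for both His4:CG33905 and His4:CG33901, 0.04 for Fib, 0.05 for nop5, 0.01 for Hsc70-4 and -0.39 for Hsp23. In the remaining lists they were -0.19 for geminin, -0.14 for Top2, 0.08 for FDY, 0.98 for Sxl, 0.47 for SPARC, -0.19 for LanB1, 0.11 for the HP1a gene, -0.18 for Caf1-55, -0.20 for aurB and 0.00 for borr. Histone copies are nearly identical, so their separate values are uncertain. Of the juvenile hormone list too few genes were tested for a list test. Kr-h1 had a log2 change of 0.24, and Jheh1 was listed at 11.9, 16.3 and 11.9 FPKM in controls and at 18.7, 0 and 11.6 FPKM in dNKAP RNAi. Median, mean and test differed in sign in 14 of 43 lists, none of them past the threshold: oxidative phosphorylation, heat shock, cell cycle, glycolysis, adhesion, Wingless, EGFR, sex-biased, extracellular matrix, chromatin silencing, JNK components, hemocyte, salivary gland and body wall muscle.

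Of the lists of markers of other cell types, 0 passed over all libraries. Camera adjusted p were 0.0714 for trachea (10 tested), 0.116 for adult muscle precursors (8), 0.144 for squamous peripodial epithelium (3) and 0.628 for larval gut (4). They were 0.761 for salivary gland (7), 0.802 for neurons and glia (5), 0.860 for larval body wall muscle (5), 0.883 for fat body (8) and 0.891 for hemocytes (10). The tracheal list was past 0.05, toward lower values, without control replicate 2 (0.0361), without dNKAP RNAi replicate 3 (0.0275) and with no filter (0.0498). The fat body gene Fbp1 was listed at 25.1, 10.9 and 0.542 FPKM in controls and at 62.5, 137 and 561 FPKM in dNKAP RNAi (limma adjusted p = 0.178), with no overlap between groups, and regucalcin measured 187 ± 121 and 253 ± 56.2 FPKM. The gut proteases Jon65Aiv and Jon65Aiii reached 45.8 and 34.8 FPKM in dNKAP RNAi replicate 2, against highest values of 1.09 and 0.738 FPKM in the other libraries. The salivary gland gene Sgs7 was also highest in that library, at 86.6 FPKM against at most 30.5 FPKM elsewhere, as was Sgs8 at 18.4 against at most 10.6 FPKM. Loss of that library left 145 genes higher and 29 lower. The hemocyte genes Ppn (131 ± 6.81 and 86.2 ± 39.2 FPKM) and Col4a1 (44.5 ± 13.7 and 52.9 ± 17.04 FPKM), and the muscle precursor genes Ama (log2 change -0.40) and Mef2 (0.26) did not pass. Nor did the tracheal genes verm (-0.20) and pio (-0.30), the muscle genes Tm1 (-0.79) and Msp300 (0.06) and the peripodial genes drm (-0.63) and odd (-0.20). drm, with a limma adjusted p of 0.0625 over all genes, was past 0.05 when adjusted over the peripodial list alone. Among genes above 0 in every library its limma adjusted p was 0.0415. loco, a regulator of G protein signalling in glia, was the 1 gene of these lists to rise over all genes and over its list alone, from 21.3 ± 0.600 to 34.9 ± 3.49 FPKM, and that call ended without any control or dNKAP RNAi replicate 2 (limma adjusted p up to 0.0679).

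A set of genes was listed at 0 in one group and well above 0 in the other. Among all genes 28 were at 0 in every control library and above 5 FPKM in every dNKAP RNAi library, and 5 showed the opposite. wus was listed at 50.7, 57.1 and 65.8 FPKM in dNKAP RNAi, RFeSP at 33.5, 40.2 and 33.6, Swim at 28.8, 28.1 and 43.6 and Dif at 28.9, 27.5 and 42.7, each at 0 in all controls. Also at 0 in all controls, agt was listed at 26.9, 27.7 and 29.8, SerRS-m at 23.7, 25.2 and 22.1, CG10581 at 27.8, 29.0 and 15.7 and net at 11.8, 9.54 and 10.6. Rtca, an RNA cyclase, was listed at 56.2, 44.0 and 38.6 FPKM in controls and Not3, a subunit of the CCR4-NOT deadenylase, at 19.7, 6.86 and 48.2 FPKM, both at 0 in dNKAP RNAi. Limma adjusted p for these genes ran from 1.19e-04 for wus to 0.0203 for Not3, whose call ended without control replicate 1 or any dNKAP RNAi replicate, with an adjusted p of 0.0801 at most. An exact 0 in these tables can be a failed estimate: Act5C, the main cytoplasmic actin gene, was listed at 0 in all 6 libraries and the ribosomal protein gene RpS2 in 4. Of 6506 tested genes 995 were at 0 in at least 1 library, including 40 of the 209 higher and 8 of the 33 lower genes. Among the 5511 genes above 0 in every library, 235 were higher and 59 lower, of which 169 and 25 were also called among all tested genes.

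Transcript usage was compared because the tables list transcripts and NKAP has a reported role in splicing. Of 1833 genes with at least 2 kept transcripts, 44 had changed usage with limma's diffSplice, Simes p and Benjamini-Hochberg adjustment. Values under a reference transcript include new assemblies closest to it, so a change of closest match between libraries can pass as changed usage. With exact matches alone 30 of 1257 genes passed, 27 of them among the 44. In sqd, which encodes an hnRNP, FBtr0082855 was listed at 156, 155 and 174 FPKM in controls and at 0 in dNKAP RNAi, while FBtr0082857 was listed at 0 in controls and at 360, 327 and 93.5 FPKM in dNKAP RNAi (adjusted p = 4.72e-09). The genes ttk, Cortactin, eIF4E1, DCP2, PNPase, vari and Idh had the next smallest adjusted p, up to 3.38e-07 for Idh, and each of the 8 named genes had a transcript listed at 0 in every library of 1 group. In PNPase the single transcript listed in controls, at 14.4, 13.2 and 16.8 FPKM, was at 0 in dNKAP RNAi, and the other was listed at 15.8, 18.9 and 12.5 FPKM there and at 0 in controls. Among 576 genes with at least 2 transcripts above 0 in every library, 2 passed, Fas3 and Pex3, and 0 of these were among the 44. The share of FBtr0075640 among the kept transcripts of Pex3, a peroxisome biogenesis gene, was 61.3 ± 5.58% in controls and 39.8 ± 1.54% in dNKAP RNAi (SD, n = 3 each; limma adjusted p = 0.0205). For Fas3, values summed under FBtr0112804 were 150 ± 9.46 and 83.5 ± 27.3 FPKM and under FBtr0081051 108 ± 40.8 and 387 ± 25.5 FPKM (limma adjusted p = 0.0205). With exact matches alone the log2 change of Fas3 was -0.32, so its rise was not seen in exact matches to its reference transcripts. haf, CG7546, Droj2, HipHop, Scamp and Exn followed at adjusted p of 0.0671 to 0.0681 and did not pass. Leaving out any 1 library gave 71 to 82 genes in place of 44, with 71 without control replicate 1 or dNKAP RNAi replicate 3, 78 and 82 without control replicates 2 and 3, and 80 and 81 without dNKAP RNAi replicates 1 and 2.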

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

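The tests of hemocyte reads, of genes that overlap Cul2 and of called genes near Cul2 were chosen only after the results were seen, and the genes listed at 0 had been noticed before their tests were written, though the split counts and overlap shares had not been computed.

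Of 5 classes of transcripts that the gene values leave out, 3 had a higher total FPKM in every dNKAP RNAi library than in any control library. Transcripts inside introns summed to at least 1127 FPKM in dNKAP RNAi and at most 19760, against 619 to 791 in controls. In dNKAP RNAi replicate 2, 1 item of 82 bases in lovit held 18631 FPKM, and 1129 FPKM were left without it. In dNKAP RNAi replicate 3, 1 item in GEFmeso held 480 FPKM, and 942 FPKM were left without it. In megabases read per gigabase of the library this class was at 0.481 to 1.32 in dNKAP RNAi and 0.286 to 0.363 in controls. That measure still counts these items, so the 1.32 of dNKAP RNAi replicate 2 rests in part on the lovit item. dNKAP RNAi replicates 1 and 3 were at 0.481 and 0.682. Intergenic transcripts summed to 501.1 to 636 FPKM in dNKAP RNAi and 332 to 399 in controls, but in megabases read per gigabase of the library the groups overlapped, at 0.440 to 0.571 against 0.381 to 0.518. Single-exon transcripts that reach into an intron summed to 614.7 to 1628 FPKM in dNKAP RNAi and 351 to 453 in controls. In dNKAP RNAi replicate 1, 1 item in RpS28b held 1105.5 FPKM, and 522.5 FPKM were left without it. In megabases read per gigabase of the library this class was at 0.616 to 1.14 in dNKAP RNAi and 0.312 to 0.556 in controls. The RpS28b item is still counted there, so the 1.14 of dNKAP RNAi replicate 1 rests in part on it. dNKAP RNAi replicates 2 and 3 were at 0.627 and 0.616. In total FPKM the other classes overlapped between groups: exonic overlap on the other strand summed to 16.3 to 27.9 FPKM in dNKAP RNAi and 9.88 to 28.9 in controls, and transcripts close to a gene to 115.8 to 194 FPKM and 66.4 to 129.

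Genes listed at 0 in every library of one group and above 5 FPKM in every library of the other numbered 33 in the comparison of control with dNKAP RNAi. The other 9 splits of the 6 libraries gave at most 12 (SD 2.47), which argues against failed estimates that fall without regard to group. Exons of another gene overlapped 81.8% of the 33 genes and 37.8% of the other 6473 tested genes, a difference of 43.97 points (Fisher's exact test, two-sided p = 4.47e-07). A candidate explanation is therefore that the estimates were lost where genes overlap, in a way that differed between the groups. A change in these genes by dNKAP RNAi stays open.

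The DNA damage response and repair list (6 of 25 genes called) and the JAK/STAT list (4 of 12) were past 0.05 toward higher values with the preset correlation, but had an adjusted p of 0.869 each with an estimated correlation. The 10 tested hemocyte markers had a median log2 change of 0.2138 (SE 0.31), against 0.31 for all 37 tested members of the 2 lists, so reads from hemocytes cannot be told apart from the rise, because the spread of the markers is too wide. The smallest adjusted p of a marker was 0.326, 3 of the markers are also in another list, and the most abundant, Ppn and Col4a1, measured 131 and 86.2 FPKM and 44.5 and 52.9 FPKM in control and dNKAP RNAi. The highest camera adjusted p of the 2 lists after median-ratio scaling or quantile normalization was 0.004907. Median-ratio scaling moves all genes of a library alike and camera compares a list with other genes, so that scaling could not test the authors' normalization. Quantile normalization could, and both lists stayed past 0.05, which argues against the authors' normalization as the whole cause. The repair list's median went from 0.33 to 0.155 there, so a part of the rise may depend on it. A response to dNKAP RNAi stays open as well.

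Cul2 rose in all 3 dNKAP RNAi libraries to a nearly constant level. The exons of 0 annotated genes overlap those of Cul2, which argues against reads of a neighbouring gene that overlaps it. Within 250 kb, 1 other called gene lay, Lamp1 (8.34 ± 1.08 and 4.47 ± 0.412 FPKM), below the 95th percentile of 4 over tested genes. A single such gene decides neither way. A difference in genetic background or an inserted transgene at the locus may account for the rise and cannot be told apart from an effect of dNKAP RNAi, since the RNAi transgene is present in 1 group alone.

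The 10 splits of 3 against 3 libraries are too few for a share under 0.05. The real split gave 242 changed genes and the highest other 14, a count reached by 1 of the 10. For transcript usage the real split gave 44 genes and the highest other 24, reached by 1 of the 10. For gene lists past the threshold the real split gave 6 and the highest other 12, and 4 of the 10 splits, the real one included, gave as many as the real one.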

How the results depend on the processing

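Tests on genes above 0 in every library, with values of 0 set to missing, with exact matches alone, with every class code but overlap on the other strand, and of lists after quantile normalization were chosen only after the results were seen. CG6066 was lower under all settings, with a log2 change of -0.90 and adjusted p of 0.134 with a replicate block and 0.587 against a minimum fold of 1.5, and of -0.96 to -0.81 with 1 library left out; elsewhere its adjusted p was 0.00871 to 0.0237. Whether the replicate numbers pair the libraries is not settled. Deviations correlated at 0.0170, 0.0683 and 0.0642 between equal numbers and at -0.116 to 0.0550 between unequal ones. Control replicate 1 and dNKAP RNAi replicate 1 correlated best with another number, and replicates 2 and 3 of both groups with their own. Higher genes numbered 72 with the block, 80 with the minimum fold and 126 to 159 with 1 library left out. Lower genes numbered 61 after median-ratio scaling, 62 after quantile normalization, 60 without a filter, 5 with the block, 7 with the minimum fold, 57 with read depth times length, 59 among genes above 0 in every library and 59 with values of 0 missing. Lists past the threshold numbered 0 with an estimated correlation, 3 with fry and 11 without a filter. With the block the lists for ecdysone response (0.0267) and for notum and hinge (0.0159) also passed. Genes with changed usage numbered 72 without a filter, 2 among transcripts above 0 in every library and 71 to 82 with 1 library left out. No gene was called the other way in any setting, but log2 changes of named genes turned sign, of which Fas3 alone was called as reported. They were after median-ratio scaling borr -0.0310, Hsc70-4 -0.0225 and Tom -0.0008761. After quantile normalization they were borr -0.004456, His4:CG33905 -0.008442, His4:CG33901 -0.005056 and arm 0.0665. There the test of the ribosomal protein list changed direction (adjusted p = 0.981), while its median stayed negative, at -0.017. With read depth times length they were HP1a -0.12, Fib -0.001473 and vg -0.14, and with values of 0 missing Jheh1 0.15, N -0.0526 and Xrp1 1.49. Exact matches alone gave Fas3 -0.32, Mef2 -0.75, Msp300 -1.01, HP1a -0.44, RpL23 -0.11, tkv -0.955, cic -0.20, Kr-h1 -0.38, Fib -0.24, Sxl -1.63, puc -0.36, wg -0.25, vg -0.45 and Xrp1 2.96. With 1 library left out the ranges that crossed 0 were -0.0657 to 0.0414 for borr, -0.34 to 0.10 for br, -0.005504 to 0.48 for Col4a1, -0.10 to 0.0573 for Egfr, -0.0258 to 0.19 for FDY and -0.0529 to 0.0913 for Fib. They were also -0.0163 to 0.0491 for Hsc70-4, -2.48 to 0.15 for Jheh1, -0.27 to 0.35 for Msp300, -0.0526 to 3.62 for N, -0.0487 to 0.10 for nop5, -0.009761 to 0.57 for RpL41, -0.14 to 0.19 for rpr, -0.14 to 0.24 for HP1a, -0.11 to 0.15 for Tom, -0.10 to 0.51 for vg and -3.92 to 1.49 for Xrp1. Apart from settings with fewer genes or libraries, the cause was not tested. Of 57 named genes called besides CG6066, 33 were called in all 6 fits with 1 library left out. The 57 do not include mre11, nbs, genes named for transcript usage alone or genes first named in the closing sections. Settings for read counts (another count test, its size factors, scaling by total count, a count minimum) were not run because the values are not counts. Depth limits low genes: confidence bounds were widest in the library with the fewest bases, dNKAP RNAi replicate 1.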

Other observations

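The tests of gene families and of iron-sulphur cluster genes, and the further repair genes, were chosen only after the results were seen; the test of genes with introns was written before its result.

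Outside the fixed repair list, 6 called genes with a known role in repair, replication or chromatin were noticed, and no test of enrichment was run on them. RPA1, which binds single-stranded DNA, rose from 89.7 ± 8.55 to 182 ± 21.3 FPKM, RfC4 from 120 ± 11.975 to 209 ± 6.18 FPKM and XRCC1, a scaffold of single-strand break repair, from 11.8 ± 1.29 to 20.5 ± 1.43 FPKM (SD, n = 3 each; limma adjusted p = 0.0122, 0.00908 and 0.0224). Ercc1 and hay of nucleotide excision repair rose by 0.63 and 0.76 on the log2 scale, and the acetyltransferase gene Gcn5 by 0.68; exons of another gene overlap each of these 3. Among 36 families of genes with a shared name, 2 were past 0.05 with the preset correlation, both of the proteasome. The Rpn genes of its regulatory particle had a median log2 change of -0.23 with 9 of 10 lower (camera adjusted p = 7.82e-04; adjusted p = 0.992 with an estimated correlation), and Rpn7, the 1 called member, fell from 250 to 191 FPKM. Its exons overlap those of CG34376, listed at 0 in all controls and at 14.6, 14.74 and 12.7 FPKM in dNKAP RNAi, so its value is uncertain. The Prosalpha genes of the proteasome core had a median of -0.30 with 8 of 8 lower and 0 called (camera adjusted p = 0.00220; adjusted p = 0.992 with an estimated correlation). After quantile normalization the camera adjusted p was 0.165 and 0.166, with medians of -0.18 for both.

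Several called genes act in iron-sulphur cluster assembly or use, among them Nfs1, the cysteine desulphurase, which rose from 41.2 ± 1.20 to 118 ± 11.6 FPKM (limma adjusted p = 0.00108); exons of other genes overlap those of Nfs1, bcn92, Nubp1 and Mocs1. The hypothesis is that the assembly genes rise as a group. The 9 tested genes left after the 6 called ones (Nfs1, bcn92, Nubp1, Nubp2, Mocs1 and Las) were set aside had a median log2 change of 0.20. Since every called member had been set aside, and Fdx1 and IscU among the rest were listed at 0 in some libraries, this value decides nothing and the hypothesis stays open. The scaffold gene IscU was listed at 0, 50.1 and 50.3 FPKM in controls and at 110, 106 and 136 FPKM in dNKAP RNAi.

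Since NKAP has a reported role in splicing, genes with introns may fall against genes without introns. The median log2 change was 0.03 for both the 4869 genes with at least 2 exons and the 622 single-exon genes. The difference was -0.00185 (SE 0.01), where the other splits ran from -0.0219 to 0.0351. The bound set beforehand against the hypothesis, a median at or above that of single-exon genes, was not strictly met. The reading that the data argue against a fall of 0.1 or more rests on the difference missing -0.1 by more than 2 SE, a reading chosen after the values were seen.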
